A study of Ovis aries with 8 samples.

How the data were processed

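The data are 8 Agilent 1-colour sheep arrays, each hybridised with Cy3-labelled RNA made from 450 ng of the total RNA of 1 fetal lung. Per the labels, 1 fetus of each of 4 sets of twins received 0.2 mg of aldosterone over 48 hours and its twin was the control, with infusions begun 5 days after surgery. Groups and replicate numbers were taken from the labels, giving 4 aldosterone and 4 control samples from separate fetuses. All arrays shared 1 slide and scan, so no slide or scan could be tested as a batch; the row of the slide was.

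The deposited scanner files hold spot intensity on a linear scale, and per the file headers the authors made them with Agilent Feature Extraction 10.1.1.1, which subtracted the background, removed spatial trends within the array and replaced values near background by surrogates. No normalization between arrays is recorded there. The authors' deposited series table holds log2 values for 12762 spots, with 12 to 262 cells empty per array and a median of 0 in each column. Setting each column against its own array showed these to be the log2 processed intensity less a constant per array, with higher values for brighter spots; the rule by which spots were listed or left empty is not given in the sources used here.

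From the files, log2 of the processed signal less the array's 75th percentile was computed over 15208 non-control spots, and spots of the same probe were averaged to 15008 probes. Spots with outlier flags were left out, which removed 41 values. The 75th percentile lay between 10.23 and 10.73 on the log2 scale, and 1 spot was saturated. Probes well above background on at least 4 of the 8 arrays were kept, 12168 in all. No probe of a named gene reported here was below background on every array of a group. Mean log2 differences between groups are given with limma's moderated standard error.

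Probes were named through a RefSeq gene table of the sheep assembly ARS-UI_Ramb_v3.0, used for names alone. Names came from the RefSeq accession for 698 probes, from a gene ID for 139, from the symbol for 497, from a synonym for 20 and from a table of older names for 155. The name in the file was kept for 124. In all 1633 probes carried 994 different names, 14 matched several genes and were left unnamed, and for 9 the file and the accession disagreed. Most probes of this array stand for unnamed transcript sequences: 10909 of the 12168 tested had no gene name, and the 1259 others stood for 808 genes. For a gene with several probes the one with the highest mean over all arrays was used. Of 399 such genes, 98 had probes of opposite sign.

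Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. The model held the group alone, since the labels name the twin sets without saying that the replicate number marks them; the fit with the number as a block was the alternative fixed in advance. After the group means were removed, the 4 same-numbered samples correlated at 0.446, 0.276, 0.28 and 0.538 across 12127 probes, against -0.449 to 0.203 for samples of different number. Every pair exceeded the 0.1 set as the threshold, so the numbers were taken to pair the samples. The threshold alone does not single out the pairs. Control replicate 2 with aldosterone replicate 1 (0.203) and control replicate 4 with aldosterone replicate 3 (0.11) exceeded it too. Removing the group means also pushes the different-numbered correlations down where the same-numbered ones are above 0, so part of the contrast is built in. The limma standard errors of single genes below still come from the fit without the block unless stated. Their median over probes was 0.201, and with the block it was 0.144. The pairing comes from the labels' twin design and this check, and same-numbered arrays also lie side by side on the slide. Over probes, the 8 arrays correlated at 0.966 to 0.989, so no pair of arrays held identical values. An exact two-sided permutation test between the groups gave p = 0.914 for the 75th percentile and p = 0.371 for the share of spots well above background, where 0.0286 is the smallest p that 4 samples against 4 allow. The first principal component held 36.8% of the variance.

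A set of 26 gene lists was fixed before the data were examined, and 21 with at least 5 measured genes were tested with camera in limma, at a preset correlation of 0.01 between genes and with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With the preset correlation 1 list passed, and with an estimated correlation 0 did. Further, 4 gene families found by probe description were added as sets after the first fits. The genes named were also fixed in advance: the 10 genes of each direction with the largest change among those past the threshold, filled up by smallest unadjusted p where too few passed; 20 transport, steroid, surfactant and matrix genes, of which 16 were measured; up to 4 members of each list by smallest unadjusted p; and at most 2 unnamed probes in each direction. The first 2 parts came to 35 genes. Of all the genes so chosen, 2 are not reported here. In list paragraphs, genes named more than once are given once.

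The procedure was tested on simulated data made from the 8 arrays, in 10 sets over 12127 probes. In each set 100 probes were changed by a log2 of 1 and another 100 by a log2 of 2. Without the block, 36.1% of probes changed by a log2 of 1 were recovered and 84.9% of those changed by 2, with 1.1 false calls per set; with the block these were 55.1%, 88.2% and 5.2. For camera, over 804 genes and 100 sets, 4.14% of unchanged lists had a p under the threshold, and a list shifted by a log2 of 1 was recovered in 100% of sets. Those sets drew each gene independently, with no effect shared within a pair. They therefore do not give camera's error rate where the genes of a list vary together. The measured cell cycle genes did so, with an estimated correlation of 0.728. The probe sets kept the pair effects of each probe but drew the rest of its spread independently. Their rates therefore do not cover other variation that many probes of an array share.

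The alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile normalization of the processed signal, the percentile over detected probes, the median, the authors' values, outlier spots kept, no filter, a filter for all 8 arrays, the replicate block, the slide row as a block, an intensity trend with robust estimation, array weights, each sample left out in turn, and the mean of a gene's probes.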

Results

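Gene expression was measured in the lungs of 8 sheep fetuses late in gestation, at about 130 days of a term of 147 days. Each of 4 sets of twins gave a fetus infused for 48 hours with 0.2 mg of aldosterone, the adrenal hormone that acts on the mineralocorticoid receptor, and a vehicle-infused twin as its control. The 2 groups therefore held 4 lungs each. The RNA of each lung was hybridised to its own 1-colour array, and all 8 arrays lay on 1 slide. Between 76.49% and 85.41% of the spots on an array were well above background. The number of arrays limits the precision of every value given here. The comparison asks which genes of the late-gestation fetal lung respond to 48 hours of raised aldosterone.

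Of 21 gene lists tested, the list of the cell division cycle was the only one to pass, and it did so only with a preset correlation between genes. All 6 measured members of the cell cycle list had higher means after aldosterone, with a mean log2 difference of 0.54 and a median of 0.62. CCNA2, the cyclin of S phase and early mitosis, had a log2 difference of 0.76 ± 0.25 (SE, n = 4 per group), and CDK1, the kinase that drives entry into mitosis, one of 0.75 ± 0.29. The list passed the camera test with the preset correlation (adjusted p = 3.09e-06), but not with an estimated one (adjusted p = 0.938). With the preset correlation, 27 of the 35 splits into 4 and 4 samples passed at least 1 list, the real one included. No single probe on the array passed limma's adjusted threshold, 229 had an unadjusted p under 0.05, and for the 3 epithelial sodium channel subunits and the surfactant proteins SFTPB, SFTPC and SFTPD the difference was smaller than its standard error.

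Across the other members of the cell cycle list, TYMS, which makes thymidylate for DNA synthesis, had a log2 difference of 0.67 ± 0.22, and the mitotic kinase AURKA one of 0.56 ± 0.20. HMMR, a hyaluronan receptor that also binds the mitotic spindle, gave 0.43 ± 0.25, and PCNA, the sliding clamp of the DNA polymerases, 0.10 ± 0.17. TYMS, CCNA2, AURKA and CDK1 were higher in the aldosterone sample of all 4 same-numbered pairs. When adjusted over the list alone, 4 of the 6 genes passed, the smallest adjusted p in limma being 0.0366, while 0 passed over all probes. With the replicate number as a block 3 passed over the list alone, TYMS, CCNA2 and AURKA, each at an adjusted p in limma of 0.0498. CDK1 did not (adjusted p in limma 0.0523). The list was singled out by its camera p in these same data, and adjustment over its genes alone leaves out that choice. Its genes also varied together, so these passes and the agreement of the pairs are not separate evidence. ASPM, a spindle pole protein outside the list, had a log2 difference of 0.80 ± 0.30. Over the alternatives these differences ran from 0.54 to 0.97 for CCNA2, 0.46 to 0.92 for CDK1, 0.46 to 0.78 for TYMS, 0.27 to 0.67 for AURKA and 0.46 to 0.99 for ASPM, and the lowest for CCNA2, AURKA and ASPM came after normexp and quantile normalization. The mean of the list by pair was 0.55, 1.19, 0.17 and 0.27. Without the aldosterone lung of replicate 2, which had the highest value of its group for 6 of the 6 genes and lay at -41.69 on the second principal component where the others lay from -10.87 to 22.23, the mean of the list was 0.34. Fry asks whether the genes of a set move one way without comparing them with other genes. The list's p in fry was 0.0527 before adjustment over the lists and 0.987 after it. With the replicate block its unadjusted p in fry was 0.102. In camera with the estimated correlation the unadjusted p was 0.0447.

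**Figure D1:**
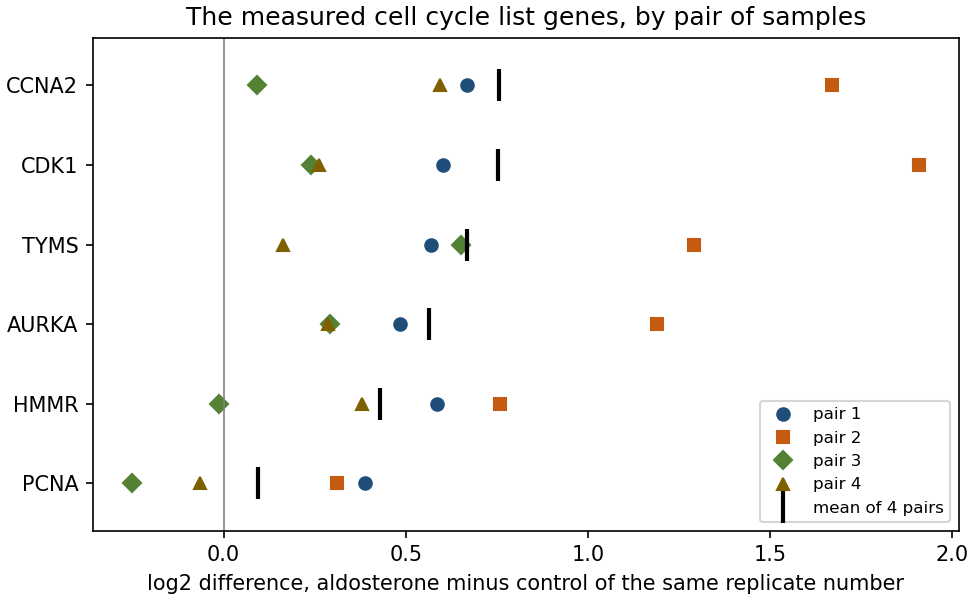
Log2 difference between the aldosterone and the control sample of each same-numbered pair, on the horizontal axis, for the 6 measured genes of the cell cycle list. Symbols are the 4 pairs and black ticks their means; the difference of CDK1 ran from 0.24 in pair 3 to 1.91 in pair 2, and PCNA lay below 0 in pairs 3 and 4.

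Sodium and water transport is the classical target of aldosterone in epithelia. Of the 13 measured genes of this list, 8 had a higher and 5 a lower mean after aldosterone, none passed the adjusted threshold, 0 passed when adjusted over the list alone, and the list did not pass (mean log2 difference 0.06, camera adjusted p = 0.793). AQP1, a water channel found mainly in endothelium, had a log2 difference of 0.55 ± 0.17 on its brighter probe and 0.53 ± 0.17 on the other. ATP1B1, a beta subunit of the sodium pump, gave -0.05 ± 0.20. The epithelial sodium channel subunits gave 0.11 ± 0.21 for SCNN1A, 0.09 ± 0.21 for SCNN1B and 0.22 ± 0.28 for SCNN1G. SCNN1A gave -0.017 after normexp and quantile normalization and -0.01 ± 0.32 on its other probe, and SCNN1G was well above background on only 2 arrays of each group. AQP5, the water channel of alveolar type I cells, gave -0.05 ± 0.32. The scaffold NHERF1 gave -0.15 ± 0.17.

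**Figure D2:**
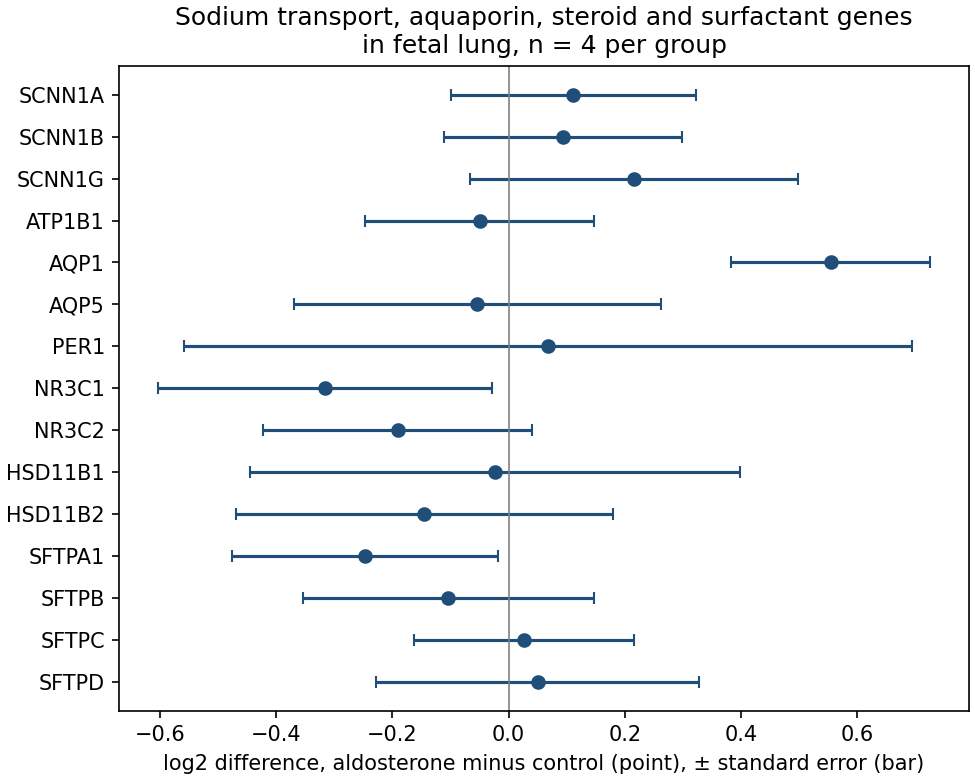
Log2 difference, aldosterone minus control, on the horizontal axis for 15 transport, steroid and surfactant genes named in advance. Points are differences of group means over 4 arrays each and bars are ± 1 standard error; AQP1 at 0.55 and NR3C1 at -0.32 are the outermost points.

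The receptors and enzymes that set the response of the tissue to corticosteroids were measured too. The mineralocorticoid receptor NR3C2 had a log2 difference of -0.19 ± 0.23 and the glucocorticoid receptor NR3C1 one of -0.32 ± 0.29. HSD11B2, which inactivates cortisol, gave -0.15 ± 0.32, and HSD11B1, which regenerates it, -0.02 ± 0.42. The clock gene PER1, a direct target of corticosteroid receptors, gave 0.07 ± 0.63 (-0.012 after normexp and quantile normalization) and was well above background on 2 control and 3 aldosterone arrays. The chaperone HSP90AA1 gave 0.11 ± 0.17 and the cell cycle inhibitor CDKN1C 0.14 ± 0.29. Of the 10 measured genes of the corticosteroid response and receptor list, 5 were higher and 5 lower, none passed, and the list did not pass (mean -0.03, median 0.01, camera adjusted p = 0.809). No probe was named here as SGK1, TSC22D3, FKBP5 or ELN, so these 4 genes were not analysed here.

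Surfactant proteins, the products of alveolar type II cells, were measured by 2 probes each. SFTPA1 had a log2 difference of -0.25 ± 0.23, SFTPB of -0.10 ± 0.25, SFTPC of 0.03 ± 0.19 and SFTPD of 0.05 ± 0.28; in the authors' values SFTPC gave -0.033 and SFTPD -0.0088. The second probe of SFTPB gave 0.05 ± 0.24, opposite in sign to the brighter one. FASN and ACLY, enzymes of fatty acid synthesis, gave 0.20 ± 0.16 and 0.09 ± 0.22. Of the 7 measured genes of the surfactant and type II cell list, 4 were higher and 3 lower, none passed, and the list did not pass (mean -0.00074, median 0.03, camera adjusted p = 0.916). The alveolar type I cell list, with IGFBP2 at 0.69 ± 0.42, ICAM1 at -0.45 ± 0.52, CRYAB at 0.29 ± 0.41 and CAV1 at -0.09 ± 0.17, had 2 higher and 4 lower genes of 6 (mean 0.05, median -0.06, adjusted p = 0.916). The airway secretory and basal cell list had 1 higher and 5 lower genes of 6, a mean of -0.23 and an adjusted p of 0.287. It passed with array weights (mean -0.46, adjusted p = 0.0309) and without the aldosterone lung of replicate 2 (mean -0.50, adjusted p = 0.00909), while without that of replicate 3 the mean was 0.02. These passes used the preset correlation; over all lungs its adjusted p was 0.97 with an estimated correlation and 0.987 in fry. Its members included SCGB3A2, a club cell secretoglobin, at -1.14 ± 0.66, LTF at -0.53 ± 0.41, ALDH1A1 at -0.21 ± 0.15 and PIGR at 0.79 ± 0.64.

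Among the structural lists, extracellular matrix had 11 higher and 7 lower genes of 18 (mean 0.10, adjusted p = 0.793), with the collagenase MMP14 at 0.28 ± 0.13, COL3A1 at 0.31 ± 0.29 and the receptors TGFBR1 and TGFBR2 at 0.41 ± 0.36 and 0.23 ± 0.21. Smooth muscle and mesenchyme had 3 higher and 3 lower genes (mean -0.04, adjusted p = 0.809), including FGF10, a mesenchymal factor for branching, at -0.26 ± 0.17, VIM at 0.16 ± 0.14, FGF7 at -0.15 ± 0.25 and CNN1 at -0.10 ± 0.19. Vascular endothelium and angiogenesis had 8 higher and 8 lower genes (mean -0.05, adjusted p = 0.809), including TEK at 0.35 ± 0.26, FLT1 at -0.23 ± 0.26 and KDR at 0.18 ± 0.22. Growth factor and lung morphogenesis signalling had 13 higher and 12 lower genes (mean 0.02, adjusted p = 0.834), with BMP7 at 0.61 ± 0.24, PTCH1 at -0.27 ± 0.26 and AREG at 0.69 ± 0.78 (-0.22 without the aldosterone lung of replicate 2). The list of striated muscle, cartilage, mesothelium and fat markers had 5 higher genes of 6 (mean 0.10, adjusted p = 0.793), with TNNC2 at 0.33 ± 0.25, LPL at 0.25 ± 0.47, PLIN1 at 0.08 ± 0.17 and LEP at 0.09 ± 0.19. The renin-angiotensin list had 1 higher and 5 lower genes of 6 (mean -0.20, adjusted p = 0.502), with ACE at -0.98 ± 0.38, AGTR1 at -0.11 ± 0.21, AGTR2 at 0.07 ± 0.15 and CYP17A1 at -0.08 ± 0.18; without ACE, which was well above background on 1 aldosterone array, the mean was -0.05.

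The means of the immune lists differed in sign, and no immune list passed. The macrophage and monocyte list had 11 higher genes of 12 (mean 0.11, adjusted p = 0.793), with CD14 at 0.42 ± 0.23, CYBB at 0.47 ± 0.38, CYBA at 0.20 ± 0.28 and ITGAM at -0.84 ± 0.65; its mean was -0.18 without the aldosterone lung of replicate 2 and -0.0047 with array weights. T and natural killer cell genes were 5 higher and 5 lower (mean 0.05, median -0.03, adjusted p = 0.9), with GNLY, a cytotoxic granule protein, at 1.62 ± 0.76 (0.72 to 2.41 over the alternatives), CD247 at 0.39 ± 0.19, IFNG at -0.62 ± 0.32 and GATA3 at -0.58 ± 0.50. Of 26 cytokine, chemokine and inflammation genes, 9 were higher and 17 lower (mean -0.22, adjusted p = 0.793), with CXCR4 at 0.77 ± 0.32, PTGS2 at -0.76 ± 0.41, MYD88 at 0.27 ± 0.16 and CXCL10 at -0.80 ± 0.58. The interferon response list had 5 lower genes of 6 (mean -0.32, adjusted p = 0.793), with ISG15 at -0.92 ± 0.94, MX2 at -0.56 ± 0.81, IRF1 at -0.46 ± 0.69 and IRF3 at 0.17 ± 0.14. Without the control lung of replicate 4, the mean was 0.30 for the cytokine list and 0.06 for the interferon list. Antigen presentation had 2 higher and 4 lower genes (mean -0.04, adjusted p = 0.834), with PSMB8 at 0.24 ± 0.17, OVAR-DRB1 at -0.27 ± 0.34, OVAR-DQA1 at -0.16 ± 0.29 and PSME2 at -0.05 ± 0.15.

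Lists on metabolism, stress and RNA content lay near 0. Hypoxia targets had 6 higher and 3 lower genes (mean 0.09, adjusted p = 0.809), with the glucose transporter SLC2A3 at 0.31 ± 0.16, HIF1A at -0.35 ± 0.24, GAPDH at 0.50 ± 0.35 and LDHA at 0.26 ± 0.25. Immediate early and heat shock genes had 6 higher and 5 lower members (mean -0.09, median 0.04, adjusted p = 0.809), with JUNB at -0.53 ± 0.76, ZFP36 at -0.28 ± 0.42 and EGR1 at -0.12 ± 0.19, and their mean was 0.11 without the control lung of replicate 4. Oxidative phosphorylation had 3 higher and 2 lower genes (mean 0.02, adjusted p = 0.893), with ATP5PO at -0.12 ± 0.15, ATP5PD at 0.19 ± 0.30, ATP5MC1 at -0.05 ± 0.17 and ATP5MC2 at 0.05 ± 0.20. Ribosomal proteins had 11 higher and 6 lower genes (mean 0.01, adjusted p = 0.916), with RPL32 at -0.10 ± 0.16, RPL13A at 0.08 ± 0.17 and RPS26 at -0.10 ± 0.23. Camera gave the direction down for the surfactant, corticosteroid and immediate early lists although their medians were above 0, and for the lists of type I cells, T cells, growth factors, oxidative phosphorylation and ribosomal proteins although their means were above 0. In the authors' values the means of the last 3 of these were below 0, at -0.035, -0.043 and -0.045.

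**Figure D3:**
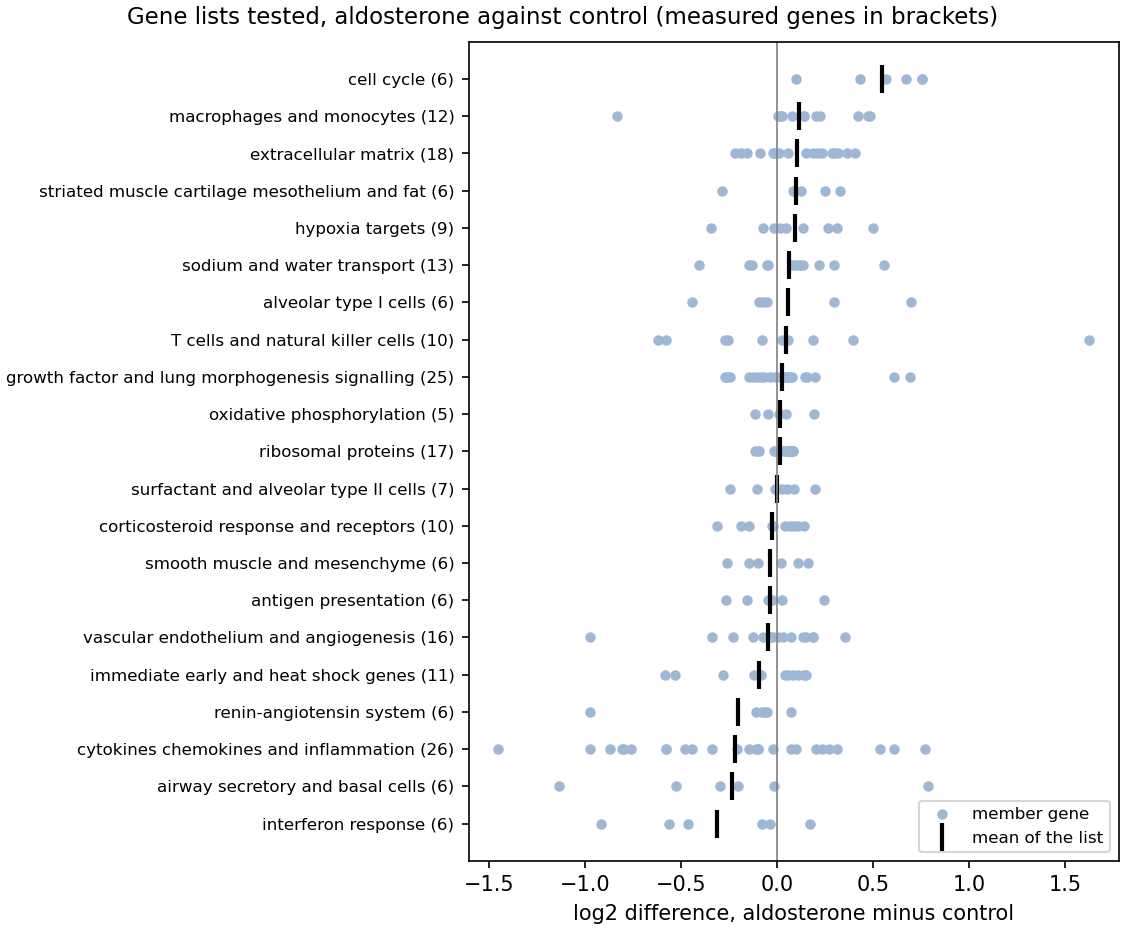
Log2 difference, aldosterone minus control, on the horizontal axis for the 21 gene lists tested, with the number of measured genes of each. Dots are member genes and black ticks list means; the cell cycle list has the highest mean, 0.54, and the interferon response list the lowest, -0.32.

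Of the lists with too few measured genes to test, ciliated airway cells had 1 (SPA17, -0.19 ± 0.21), B cells and immunoglobulins 1 (CR2, 0.16 ± 0.89), neutrophils 2 (LTF, given above, and CATHL3), red blood cells 3 (HBB -0.56 ± 0.58, CA1 -0.76 ± 0.86 and AHSP -0.72 ± 0.99, or ± 0.29 with the replicate number as a block, lower in 4 of 4 pairs), and sex-linked genes 0.

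The named genes with the smallest unadjusted p did not pass the adjusted threshold and are given by that rank. Ranking by p in these data favours genes whose pairs agree, so agreement of the pairs below is not separate support. Beyond those above, the higher side held SLC7A5, a transporter of large neutral amino acids, at 0.54 ± 0.15, and DLL4, a Notch ligand of tip endothelial cells, at 0.47 ± 0.16, both higher in 4 of 4 pairs. The steroid-metabolising CYP3A24 gave 0.55 ± 0.20. Prolactin (PRL) gave 0.95 ± 0.35 but was well above background on 2 control and 3 aldosterone arrays. On the lower side stood 4 cathelicidins, antimicrobial peptide precursors of myeloid cells: SC5 at -1.27 ± 0.49, CATHL3 at -1.20 ± 0.40, BAC5 at -1.07 ± 0.45 and CATHL1B at -0.98 ± 0.46, each lower in the aldosterone sample of all 4 pairs. FCER1A, the mast cell and basophil receptor for IgE, gave -0.99 ± 0.49, and the histamine receptor HRH2 -0.45 ± 0.18 with its other probe opposite in sign. PRKAA2, a catalytic subunit of AMP-activated kinase, gave -0.83 ± 0.30 and the follicle stimulating hormone receptor FSHR -0.82 ± 0.28, each well above background on 4 control and 2 aldosterone arrays. ACACA, which makes malonyl-CoA for fatty acid synthesis, gave -0.77 ± 0.32. ACE, on a probe made for the testis isoform of the enzyme, gave -0.98 ± 0.38 and was well above background on 4 control arrays and 1 aldosterone array. These sizes depended on the processing and on single lungs. Over the alternatives SLC7A5 ran from 0.11 to 0.63, DLL4 from 0.24 to 0.55, CYP3A24 from 0.14 to 0.71, PRL from 0.14 to 1.16, PRKAA2 from -1.09 to -0.16, FSHR from -1 to -0.12, ACACA from -0.95 to -0.27 and ACE from -1.36 to -0.18. The ranges were -1.91 to -0.74 for SC5, -1.75 to -0.86 for CATHL3, -1.78 to -0.68 for BAC5, -1.70 to -0.61 for CATHL1B, -1.53 to -0.68 for FCER1A and -0.55 to -0.31 for HRH2.

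Other probes of a gene were opposite in sign to the one reported for NHERF1, TGFBR1, PLIN1 and LEP (1 of 1 each), TEK and FLT1 (1 of 2 each), KDR (2 of 3), GAPDH (2 of 4) and ATP5MC1 (1 of 3). Of the 20 lists that did not pass, 17 had a mean that changed sign under at least 1 alternative.

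Single lungs stood apart from the rest of their group for some of the genes named. The control lung of replicate 4 was above the other controls for ICAM1, GATA3, IRF1, JUNB, ZFP36 and SFTPD. The aldosterone lung of replicate 1 was below its group for ATP1B1, SFTPC and RPL13A, that of replicate 2 below for PER1 and above for AREG, and that of replicate 4 above for TGFBR1, FGF7, PSMB8 and OVAR-DQA1. Among the controls, replicate 3 was below for GNLY and replicate 2 for LPL.

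Over the whole array, limma called 0 of 12168 probes at an adjusted p of 0.05, and 0 with the replicate number as a block. At an unadjusted p under 0.05, limma gave 229 probes, 155 higher and 74 lower after aldosterone, where 608.4 would be the nominal number; with the paired block it gave 539, 343 higher and 196 lower, and with array weights 1280, above the nominal number. The share of higher probes was 67.7% of the 229. It was 52.3% when arrays were centred on their medians (104 higher, 95 lower) and 43.3% in the authors' values (88 higher, 115 lower). These centrings move nearly all probes by the same amount, so the share depends on that choice. Of the 229, named genes supplied 26 at 1 probe per gene, 18 higher and 8 lower, and probes without a gene name 191. The unnamed probes of smallest unadjusted p were A_70_P052856 at 1.85 ± 0.37 and A_70_P004486 at 0.69 ± 0.15 on the higher side, and A_70_P054656 at -2.02 ± 0.46 and A_70_P037926 at -0.87 ± 0.20 on the lower. The count was 383, 146, 144 and 387 without the control of replicate 1, 2, 3 and 4, and 422 without the aldosterone lung of replicate 1.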

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

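Of the tests below, those of genes that vary together, of the spread between pairs, of the position on the slide and of the splits for adjusted calls were chosen after the results they bear on had been seen. The other tests were also written down after the first fits, but before the value that each of them measures had been seen. Normalized log2 signals below are relative to the 75th percentile of the array.

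In 19 of 220 groups of 4 values, 1 value stood apart from the other 3 by more than the limit of Dixon's ratio. Chance flags about 1 in 20 groups, which comes to 11 here. The control lung of replicate 4 was the one apart for ICAM1 (3.04, others up to 0.85), GATA3 (2.08, others up to 0.07), IRF1 (1.42, others up to -1.60), JUNB (1.11, others up to -2.04), ZFP36 (2.35, others up to 0.75) and SFTPD (3.77, others up to 2.98). Its array also had 85.41% of spots well above background, against 80.42% to 81.03% on the other control arrays, and 971 surrogate values, against 1532 to 1546. The aldosterone lung of replicate 4 stood apart for TGFBR1 (-4.30, others up to -5.73), FGF7 (-0.26, others up to -1.18), PSMB8 (-0.48, others up to -0.73) and OVAR-DQA1 (0.10, others up to -0.11). The aldosterone lung of replicate 1 was lower than the others for ATP1B1 (2.53, others from 3.13), SFTPC (7.97, others from 8.57) and RPL13A (5.34, others from 5.78). The aldosterone lung of replicate 2 was lower for PER1 (-7.69, others from -5.87) and higher for AREG (0.17, others up to -3.21). Among controls, replicate 3 was lower for GNLY (-5.07, others from -4.23) and replicate 2 for LPL (-3.46, others from -1.54).

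The higher cell cycle list was weighed against technical explanations. For the scaling of the arrays, the lowest mean of the list under 5 other scalings was 0.359, and the list passed under each. This was above the bound of 0.272 by more than the SD of 0.0715 between scalings, which is not an error of the mean. The percentile over detected probes, the median and the authors' values change little but a constant per array, so they could hardly reach the bound. Quantile normalization gave 0.511 and normexp with it 0.359. These argue against scaling as the source of the whole difference, but its size depended on the processing. Genes that vary together between animals are a candidate explanation for the small camera p, as their estimated correlation was 0.728 and the adjusted p with it 0.938. A single pair of twins cannot be told apart, because the mean without the pair of largest difference was 0.329 with an SE of 0.114 between the remaining 3 pairs, although all 4 pairs lay above 0. Of the 8 splits that part all 4 pairs, 1, the real split, gave so small a camera p (1.47e-07, against 3.84e-07 for the next), but 8 splits are too few for a share under 0.05. With all 4 pairs above 0, the real split also had to have the largest list mean of the 8. The list was moreover singled out by its p in that split, so no conclusion is drawn from this rank. An effect of aldosterone on cell division stays open as well.

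The number of probes at an unadjusted p under 0.05 was below the nominal number, 229 against 608.4, but above it with array weights, at 1280. A spread between pairs of twins is consistent with this, since the block on the replicate number brought the count to 539. The position on the slide cannot be told apart from the pairing: neighbouring arrays of different number correlated at 0.103, below the lowest same-numbered 0.276 by less than the SD of 0.201, and only 2 such neighbours exist. The median count was 488 in the 27 splits that leave a pair together and 156 in the 8 that part all pairs. Some of the 27 also divide the rows of the slide unevenly, and the slide row as a block gave 344. Where each row was divided evenly, splits that leave a pair together gave 239 to 791. The 8 that part all pairs, which also divide the rows evenly, gave 95 to 379. The ranges overlap, but uneven rows alone do not account for the gap. Place within a row was not separated from the pairs. No biological explanation for this pattern was tested.

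The same 8 splits were run for each count, and they are too few for a share under 0.05. For adjusted calls, 8 of the 8 splits gave as many as the real 0, which any split must, so this comparison decides nothing. The highest other was 0. Among all 35 splits into 4 and 4, 4 splits had calls, up to 40. The split with 40, which also had the highest unadjusted count, 2913, set replicates 1 and 2 against 3 and 4, the same division as the 2 rows of the slide. At an unadjusted p under 0.05, 2 of the 8 splits gave as many as the real 229, with 379 the highest other, and with the block 4 gave as many as 539, with 1040 the highest other. For gene lists past the threshold, 7 of the 8 splits gave as many as the real 1, with 4 the highest other. Among all 35 splits, 27 passed at least 1 list, the real one included. A pass of some list with the preset correlation was therefore common under other groupings.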

How the results depend on the processing

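Some alternatives were chosen after the data had been seen: other values or array weights combined with the replicate block, 4 added gene families, and an estimated correlation with the block. The count of 0 adjusted calls in limma held under every alternative run. Signal over background limits SCNN1G, PER1, PRL, PRKAA2, FSHR, ACE, ACACA, IFNG, PTCH1 and ITGAM, which were not well above background on every array. The median and the authors' values differ from the fit by a constant per array, apart from outlier spots and empty cells in the authors' values. They therefore moved the differences of nearly all probes by the same amount. The median difference over probes was 0.00737 in the fit, -0.0318 with the median and -0.0499 in the authors' values. For the other shifts below the cause was not tested, apart from the estimated correlation and the block, weighed above, and the fewer samples where 1 is left out.

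The count at an unadjusted p under 0.05, 229, became 539 with the replicate block, 344 with the slide row as a block and 1280 with array weights. With the paired block it was 525 after normexp, 519 after quantile normalization, 541 with the median, 600 in the authors' values, 527 with the percentile over detected probes and 544 with array weights. Leaving out 1 sample gave 144 (without control replicate 3) to 422 (without aldosterone replicate 1). The block changed no call over all probes or lists, and of the cell cycle genes adjusted over their list alone it left 3 of 4 passing, CDK1 having an adjusted p of 0.0523. The count of lists past the threshold, 1, became 2 with array weights and ranged from 1 to 2 when 1 sample was left out, the second being airway secretory and basal cells (-0.46, adjusted p = 0.0309 with array weights, and -0.50, adjusted p = 0.00909, without aldosterone replicate 2). It became 0 with an estimated correlation, with fry, and with each of these combined with the block. In these the cell cycle mean stayed 0.544, with an adjusted p of 0.938, 0.987, 0.801 (fry with the block) and 0.978 (estimated correlation with the block). Leaving out 1 sample gave cell cycle means of 0.341 to 0.664 and adjusted p of 2.69e-08 to 0.00346.

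None of the 102 genes reported passed under any alternative, with 19 or 20 alternatives run per gene and 2030 results in all. By alternative, 91 to 102 kept their sign, where the filter for all arrays left 92, all of the same sign. The blocks, the intensity trend and the filters leave the difference of a gene measured on every array unchanged. Under these a change of sign was not possible. By more than 1.5-fold, 35 of the 102 were smaller and 3 larger with normexp, 16 and 23 with array weights, 12 and 12 in the authors' values, 11 and 5 with the median, 7 and 1 with quantile normalization, and 11 to 20 and 10 to 20 when 1 sample was left out. The sign changed in 79 of the 2030 results, of which 17 kept all samples. With array weights these gave ATP1B1 0.0226, HSD11B1 0.0308, AQP5 0.201, ICAM1 0.0209, CRYAB -0.00956, OVAR-DQA1 0.128, IRF1 0.178, ZFP36 0.0615 and LEP -0.0235; with normexp SCNN1A -0.0167, PER1 -0.0123 and PLIN1 -0.0091; in the authors' values SFTPC -0.0326, SFTPD -0.0088 and ATP5MC2 -0.0123; and for SFTPC -0.0243 with quantile normalization and -0.0128 with the median. With 1 sample left out, the range was for SCNN1A -0.0486 to 0.229, SCNN1B -0.0629 to 0.238, ATP1B1 -0.165 to 0.11, PER1 -0.205 to 0.615, HSD11B1 -0.25 to 0.297, HSD11B2 -0.467 to 0.0176, SFTPB -0.266 to 0.0706, SFTPC -0.05 to 0.188, SFTPD -0.125 to 0.268 and AQP5 -0.251 to 0.205. Further ranges were CDKN1C -0.0636 to 0.326, ACLY -0.0552 to 0.228, ICAM1 -0.701 to 0.167, CRYAB -0.115 to 0.562, CAV1 -0.167 to 0.0258, CNN1 -0.2 to 0.0121, CYBA -0.00802 to 0.413, OVAR-DRB1 -0.53 to 0.0343, OVAR-DQA1 -0.374 to 0.123 and PSME2 -0.137 to 0.0601. Further ranges were MX2 -1.11 to 0.12, IRF1 -0.799 to 0.36, AREG -0.218 to 1.13, JUNB -0.946 to 0.313, ZFP36 -0.468 to 0.165, EGR1 -0.2 to 0.0319, ATP5PD -0.0509 to 0.425, ATP5MC1 -0.157 to 0.0418 and ATP5MC2 -0.051 to 0.214. Further ranges were RPL32 -0.179 to 0.00229, RPL13A -0.0265 to 0.194, RPS26 -0.265 to 0.0328, AGTR1 -0.247 to 0.0495, AGTR2 -0.0415 to 0.133, CYP17A1 -0.185 to 0.0288, LPL -0.259 to 0.476, PLIN1 -0.0133 to 0.194 and LEP -0.0138 to 0.207.

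Of the other 20 lists, 17 changed the sign of their mean under at least 1 alternative. This came to 50 of 500 results, counted by list and alternative. The blocks, the intensity trend, an estimated correlation and fry cannot change the mean of a list, so in those results the sign was fixed. With array weights the means were 0.0229 for corticosteroid response, 0.0792 for surfactant, 0.0335 for endothelium, -0.0922 for T cells, -0.00468 for macrophages, 0.0277 for antigen presentation and 0.0584 for cytokines. In the authors' values they were -0.00575 for type I cells, -0.0116 for T cells, -0.0351 for growth factors, -0.0432 for oxidative phosphorylation and -0.0446 for ribosomal proteins; with the median, -0.0153, -0.0234 and -0.0248 for the last 3. Growth factors gave -0.00136 with normexp and -0.00464 with quantile normalization, surfactant 0.00665 with the mean of a gene's probes, endothelium 0.0157 with the filter for all arrays, and without a filter oxidative phosphorylation gave -0.000506 and the renin-angiotensin list 0.121. With 1 sample left out, the range of the mean was for corticosteroid response -0.0907 to 0.0472, surfactant -0.0798 to 0.137, type I cells -0.0698 to 0.203, airway secretory cells -0.501 to 0.0204, smooth muscle -0.141 to 0.014, endothelium -0.101 to 0.046, T cells -0.0519 to 0.184 and macrophages -0.184 to 0.3. Further ranges were antigen presentation -0.139 to 0.148, cytokines -0.416 to 0.296, interferon response -0.686 to 0.0621, immediate early genes -0.303 to 0.108, oxidative phosphorylation -0.12 to 0.0938, ribosomal proteins -0.0693 to 0.116 and striated muscle and fat -0.15 to 0.218.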

Other observations

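The gene families, the probes looked up one by one and the tallies of list members below were chosen after the first results had been seen. Probes described as immunoglobulin chains, the antibody products of B cells, had 12 of 15 measured members higher after aldosterone, with a mean log2 difference of 0.27 and a camera p of 0.00729. Adjusted together with the lists this was 0.0911, and the p with an estimated correlation was 0.146, so the family did not pass. MHC class II chains, carried by antigen-presenting cells, had 2 of 9 higher and a mean of -0.35, with a camera p of 0.039, an adjusted p of 0.244 and a p of 0.405 with an estimated correlation. MHC class I chains, 15 probes, gave a mean of 0.14 and an adjusted p of 0.749 in camera. T-cell receptor chains, 9 probes, gave a mean of -0.07 and an adjusted p of 0.674 in camera.

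Each of the 6 probes of the cathelicidins SC5, CATHL3, BAC5 and CATHL1B was lower in the aldosterone sample of all 4 pairs, and none passed the adjusted threshold. Beside the 4 given in the report, the other BAC5 probe gave -1.04 ± 0.46 and the other CATHL1B probe -1.10 ± 0.44. Probes of the same gene are not independent. The cathelicidins were also named for their small p in these data, which favours pairs that agree, so the agreement is not separate support. LTF, another neutrophil granule product, gave -0.53 ± 0.41. An unnamed probe whose description in the file gives a likeness to bovine cyclin B1, A_70_P003401, had a log2 difference of 0.66 ± 0.32 and was higher in 3 of 4 pairs.

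The aldosterone lung of replicate 2, which stood apart on the second principal component, had the highest value of its group for 6 of the 6 cell cycle genes, 9 of the 12 macrophage and monocyte genes and 14 of the 26 cytokine and inflammation genes. The control lung of replicate 4 had the highest value of its group for 7 of 7 surfactant, 6 of 6 antigen presentation, 23 of 26 cytokine and inflammation and 8 of 12 macrophage and monocyte genes. The control lung of replicate 1 had the lowest value of its group for 16 of 17 ribosomal protein genes and 5 of 5 oxidative phosphorylation genes, and the aldosterone lung of replicate 1 for 15 of 17 ribosomal protein genes. The aldosterone lung of replicate 4 was highest for 5 of 6 genes of striated muscle, cartilage, mesothelium and fat.

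Without the member of largest difference, the mean of the airway secretory and basal cell list was -0.05 (SCGB3A2 left out) and that of the cell cycle list 0.50 (CCNA2 left out). The sign of the mean changed for T and natural killer cells (-0.13), type I cells (-0.08), surfactant (0.04), oxidative phosphorylation (-0.03), endothelium (0.02), smooth muscle (0.0083), antigen presentation (0.0067), corticosteroid response (0.006) and growth factors (-0.0040).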
